A study of Mus musculus with 6 samples.

How the data were processed

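The samples were sciatic nerves of mouse pups of mixed strain on postnatal day 2, per the labels. The perineurium had been removed, total RNA was extracted with a kit for lipid-rich tissue, and biotin-labelled RNA was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. Groups were taken from the sample titles, with 3 dKO samples (Dhh-Cre positive) and 3 control samples, and arrays are named by group and replicate number. The series' design text counts 3 mutants and 3 littermates, but no label says how many nerves or pups went into each RNA sample, so p-values measure the spread between these samples.

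The deposited values are log2 expression per probe set, from 1.66 to 14.94. GCOS 1.2 and GCRMA are named in the submitters' processing notes, without their settings. The log2 scale was read from the values, because neither the labels nor a file header states it. The median was 5.77 on every array and the sorted values of the 6 arrays differed by at most 0.01 at any rank, so the values had been made equal in distribution before they were deposited. Such scaling fixes the overall level of each array, and a change of all genes in 1 direction would not be seen. GCRMA estimates background from probe sequence, so values under the low-value limit have little meaning as levels. No 2 arrays held identical values. No per-sample columns other than those of the 6 arrays were present.

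Probe sets were named from the platform annotation. Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were not named here. Symbols were updated through gene IDs with a RefSeq table of mouse assembly GRCm38.p6, in which the IDs of 204 named probe sets were not found and kept their given name. No coordinates were used except to find which genes neighbour each other in that table. Of several probe sets of a gene, the one with the highest mean over all 6 arrays was used, and 9012 of 18194 genes had more than 1. Genes with a log2 value of at least 4 on at least 3 of the 6 arrays were tested, which left 14550 genes and removed 3644. Genes and list members that were not named here were not analysed here.

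The comparison of dKO with control was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested, a threshold of 0.05 and no covariates. All adjusted p-values of genes come from this fit and are two-sided. Those of single probe sets were adjusted over all probe sets. Where all 3 arrays of a group were under the limit of 4, the fold is a lower bound with values under the limit set to 4. Where 2 of the 3 were under it, the fold was taken in the same way, except for Uty, which was not called.

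The rule for named genes gave 128 genes: Hdac1 and Hdac2, the 10 higher and 10 lower genes with the largest change whose groups did not overlap, a set of genes known in this field, and up to 4 called members of each list (up to 2 where 0 passed). Another gene fixed in that rule was not analysed here. Members named in addition because a count was of 5 or fewer, or as a contrast, were chosen after their values were seen. These were Tead1, Mvk, Elovl5, Igf1r, Hey1, Diablo, Hdac6, Gria2, Syp, Tyrobp, Twist1, Col1a1, Col3a1, Eif2s3y and Nefl. Among 68 named genes with more than 1 probe set above the limit, 0 had a probe set called in the opposite direction.

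The 33 gene lists, 21 of pathways and 12 of cell type markers, were written from general knowledge. Atf3, Btg2, Cdkn1a, Egr1, Erbb3 and Sox10 are each on 2 lists, and Erbb3 and Sox10 stayed in the pan-Schwann list. Each list was tested with limma's camera with a preset correlation between genes of 0.01, which compares it with all other genes, adjusted over the 33 lists. Of these, 12 passed, and 0 passed with the correlation estimated from the 6 arrays, where 1 had an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move on balance in 1 direction without comparison to other genes, called 10 lists. These included the apoptosis and pericyte lists, which camera did not call, and left out the axon contact, p53, perineurial and macrophage lists (adjusted p = 0.0504, 0.0618, 0.0613 and 0.127). Medians of lists that camera did not call moved by over 1.5 times or changed sign with some array left out, except for the Wnt, endothelial and pericyte lists. The difference between the mean of the myelin list and the mean of the pan-Schwann list was compared by an exact permutation test.

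The gene fit was tested on simulated data for 14550 genes with the spread of these arrays and 200 changed genes. It recovered 53% of genes changed by a log2 of 1 and 92% of those changed by a log2 of 2, and 4.61% of the genes called were not changed. Only 200 of 14550 genes were changed there, whereas 3198 were called in the real data. The adjustment depends on how many genes change, so these shares may not hold for the real comparison. The list test called 2.5% of 200 unchanged lists of 15 genes and 100% of 100 lists shifted by 0.7. The simulated genes varied independently of each other, whereas estimated correlations within the real lists reached 0.783 (macrophage list). The simulation therefore cannot tell whether the preset correlation holds for these lists. The low-value limit, the fit, the list tests, the lists, the rule for named genes and the alternatives below were fixed before the data were examined, except where a choice is said to be later. The alternatives were the low-value limit, normalization, the probe set of a gene, the prior of the variance, array weights, a block for the replicate number, and leaving out each array. A pseudocount was not varied, because the values were already logarithms. Xist level as a covariate and the list of histone deacetylases without the targeted genes were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.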

Results

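Gene expression was measured in sciatic nerves of mouse pups on postnatal day 2, when Schwann cells, the glial cells of peripheral nerves, begin to form myelin. In the double knockout (dKO) both Hdac1 and Hdac2, which encode class I histone deacetylases, had been deleted in Schwann cells with a Cre recombinase driven by the desert hedgehog (Dhh) gene. Nerve samples of 3 dKO mutants were compared with those of 3 control littermates, as counted in the design text. Each nerve sample was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array after the perineurium, the sheath around the nerve, had been removed. Values are log2 expression, given as mean ± SD with n = 3 per group, and every change is dKO minus control with its standard error (SE). The number of arrays limits the precision, and the median SE of a log2 change was 0.17. The comparison asks how gene expression at the start of myelination differs in nerves whose Schwann cells lack both deacetylases.

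The targeted genes were lower on all 3 dKO arrays. Hdac1 went from 10.41 ± 0.06 in control to 8.86 ± 0.11 in dKO nerves, a log2 change of -1.55 (SE 0.13, adjusted p = 0.000271), which left 34.1% of the control level. Hdac2 went from 12.33 ± 0.01 to 11.07 ± 0.23, a log2 change of -1.26 (SE 0.15, adjusted p = 0.00103), which left 41.8%. Of the other 2 Hdac2 probe sets, 1 fell by 1.01 and 1 dim probe set did not pass the test (log2 change 0.13, adjusted p = 0.640). With the 3 averaged, the Hdac2 change was -0.71. The labels do not say which exons were deleted, so whether each probe set lies in the deleted part was not checked here. The RNA came from all cells of the nerve sample, and cells other than Schwann cells keep both genes. These percentages are therefore not levels within Schwann cells. Hdac3, another class I deacetylase, had a log2 change of 0.30 (SE 0.17, adjusted p = 0.243), and of 0.17 without dKO 3.

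Genes of myelin and of cholesterol synthesis had the lowest median changes of the 33 lists. Of 14550 genes tested, 3198 (22.0%) changed at an adjusted p under 0.05, 1833 higher and 1365 lower in dKO nerves. The change was at least 2-fold for 1508 genes, 874 higher and 634 lower. All dKO values lay on one side of all control values for 41.0% of genes, against 10% by chance. When each array was centred on its median over the tested genes, higher genes made up 49.4% of those called, against 57.3% as deposited. The equal medians of 5.77 given above were over all probe sets. Over the 14550 tested genes the arrays correlated at r = 0.981 to 0.988 within control and at 0.980 to 0.991 within dKO. Between the groups they correlated at 0.925 to 0.963. The first principal component held 69.5% of the variance and separated the groups. Control 2, dKO 2 and dKO 3 had high levels of Xist, the transcript of the inactive X chromosome (11.55, 11.67 and 11.24). The other 3 arrays had Xist levels of 4.14 to 5.31 and high levels of the Y-linked gene Eif2s3y, so both sexes were in both groups.

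Csn3, which encodes the milk protein kappa-casein, rose to 10.02 ± 0.08 in dKO nerves from values under the low-value limit of 4 on all control arrays. With control values set to that limit it was at least 64.8-fold higher in dKO, on the 1 of its 2 probe sets that was above the limit. Cytl1, which encodes a small secreted protein, rose by 5.80 (SE 0.21), and Crabp1, a cellular retinoic acid binding protein, rose by 5.52 (SE 0.35). Cacna1b, the pore-forming subunit of N-type calcium channels, rose by 5.51 (SE 0.29), with 3 of its 4 probe sets called. Gprin3, Aldh1a7, Arhgap15 and Acaa1b had log2 changes of 4.10 to 4.50. Cacna1b, Gprin3 and Acaa1b were under the limit on 1 control array each, and with that value set to the limit they were 40.2-fold, 19.4-fold and 17.0-fold higher. Col25a1 and Cadps completed the 10 highest fitted changes. Their controls were all under the limit, which makes them at least 23.3-fold and 6.01-fold higher and leaves the rank of Cadps to values under the limit. Only 1 of the 2 Col25a1 probe sets was called. With all probe sets of a gene averaged, the change was 3.42 for Csn3, 3.14 for Cacna1b, 2.76 for Col25a1 and 2.62 for Arhgap15. The adjusted p of these 10 genes was 0.000418 or lower.

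Mag, which encodes myelin-associated glycoprotein, fell from 10.61 ± 0.19 to 5.98 ± 0.95, a log2 change of -4.63 (SE 0.41, adjusted p = 0.000285). Pllp, which encodes the myelin protein plasmolipin, fell by 4.33 (SE 0.53), and Ncmap, a gene of noncompact myelin, fell by 4.25 (SE 0.52). Cdh1, the E-cadherin of junctions within the Schwann cell sheath, fell by 4.25 (SE 0.77). Ddn, Cldn19, Fa2h, Pmp2 and Kcnk1 had log2 changes of -4.15 to -3.95. The tight junction gene Marveld3 was also among the 10 lowest fitted changes. It went from 7.59 ± 0.51 to values under the limit on all dKO arrays, so it was at least 12-fold lower and its rank rests on such values. With its 3 probe sets averaged its change was -2.12. The adjusted p of these 10 genes was 0.00636 or lower.

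All 15 tested genes of the list of myelin proteins and lipid enzymes fell in dKO nerves, and all 15 passed when adjusted over the list alone. The list held 19 genes, of which 15 were measured here under their own name, and the median log2 change was -3.12. Pmp2, a lipid-binding myelin protein, fell from 12.47 ± 0.17 to 8.50 ± 1.06, and Drp2, a dystroglycan-associated protein of the outer sheath, fell by 3.76 (SE 0.46). The gap junction gene Gjb1 was under the limit on 2 of the 3 dKO arrays, and 3.84-fold lower in dKO with those values set to the limit (adjusted p = 0.000305). Mbp and Pmp22, which encode proteins of compact myelin, fell by 1.37 (SE 0.26, adjusted p = 0.00734) and 1.67 (SE 0.28, adjusted p = 0.00440). Their control levels of 14.09 ± 0.04 and 14.04 ± 0.01 lay near 14.94, the highest value on the arrays, and the 8 Mbp probe sets fell by 1.07 to 2.91. The list stood below other genes in camera (adjusted p = 2.69e-12 over 33 lists), and not with an estimated correlation between genes (adjusted p = 0.484). The fall was smaller in dKO 1, whose mean over the list was -2.02 relative to the control mean, against -3.40 in dKO 2 and -3.12 in dKO 3.

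**Figure D1:**
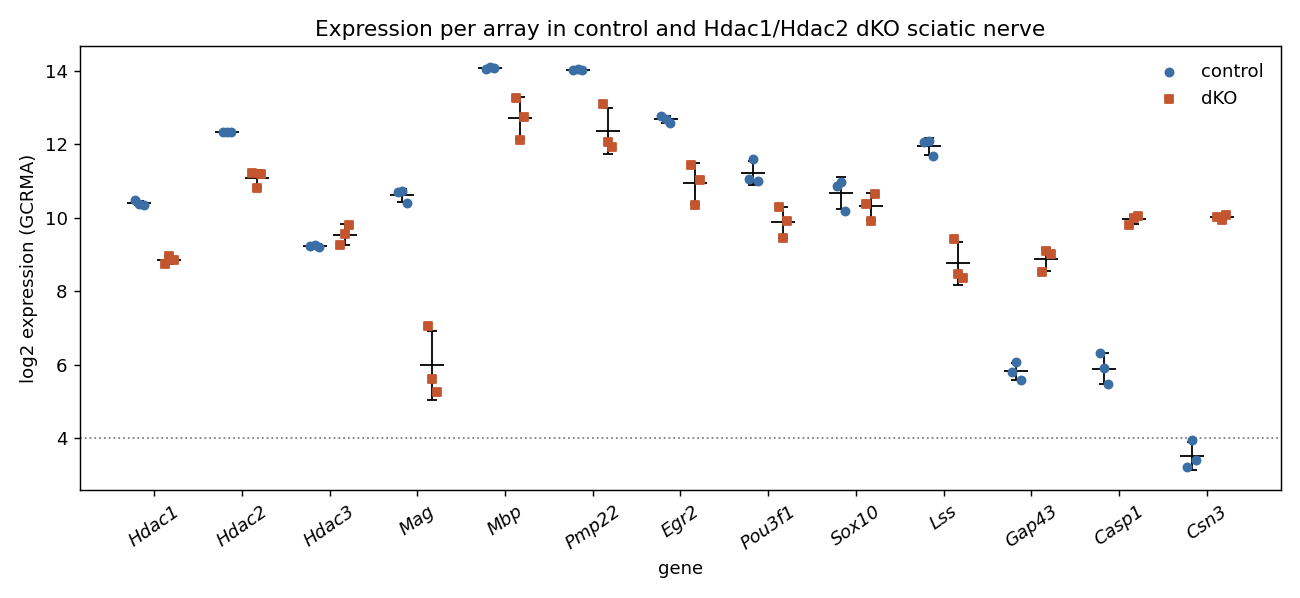
Log2 expression (vertical axis) of 13 genes (horizontal axis) on each of the 6 arrays, with control as circles, dKO as squares, black bars for the mean ± SD (n = 3) and a dotted line at the low-value limit of 4. Mag stands at 10.61 in control and 5.98 in dKO and Csn3 lies under the limit in control and at 10.02 in dKO, whereas Hdac3 and Sox10 did not pass the test.

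Of the 10 promyelinating transcription factors, 4 fell and 1 rose (5 and 1 adjusted over the list alone). Egr2, the zinc finger factor that drives myelin genes, fell from 12.68 ± 0.10 to 10.94 ± 0.56, a log2 change of -1.74 (SE 0.26, adjusted p = 0.00246). Pou3f2 fell by 1.72 (SE 0.35), and Pou3f1, a POU factor of promyelinating Schwann cells, fell by 1.34 (SE 0.25, adjusted p = 0.00664), with 1 of its 2 probe sets called and a change of -0.81 when both were averaged. Tead1 fell by 0.82, a call that was lost without control 1, control 2, control 3, dKO 2 or dKO 3 (adjusted p up to 0.123). Nfatc4 rose by 1.15 on 1 of 3 probe sets, and its change was 0.22, not past the threshold, when the probe sets were averaged. Sox10, the factor that specifies the Schwann cell lineage, had a log2 change of -0.36 (SE 0.26, adjusted p = 0.371), which ran from -0.61 without control 3 to -0.17 without dKO 2. As a list these genes did not pass in camera (median -0.58, and -0.32 without control 1, adjusted p = 0.0697), and they passed without control 3 or dKO 1 (adjusted p = 0.0270 and 0.0225), with probe sets averaged (0.0366) and with an intensity trend (0.0458). The estimated correlation gave an adjusted p of 0.688.

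All 19 tested genes of cholesterol synthesis were lower in dKO nerves, with a median log2 change of -1.86, and all 19 passed when adjusted over the list alone. The call of Mvk was lost without control 1, control 2, dKO 1 or dKO 2 (adjusted p up to 0.0616), which left 18. Lss, which encodes lanosterol synthase, fell from 11.95 ± 0.22 to 8.76 ± 0.59 (log2 change -3.19, SE 0.28, adjusted p = 0.000285). The sterol enzymes Msmo1, Sc5d and Cyp51 fell by 2.52, 2.18 and 1.95 (SE 0.19, 0.14 and 0.16). Of 14 fatty acid synthesis genes, 8 fell and 2 rose (10 and 2 over the list alone), with a median of -0.97. The elongases Elovl7 and Elovl6 fell by 3.59 (SE 0.52) and 1.90 (SE 0.28), and Acaca, which encodes acetyl-CoA carboxylase, fell by 1.31 (SE 0.17). The genes that rose were Me1, the cytosolic malic enzyme (1.44, SE 0.15), and the elongase Elovl5 (0.92). Both lists passed in camera (adjusted p = 1.13e-16 for cholesterol and 0.00173 for fatty acid synthesis), and neither passed with an estimated correlation (adjusted p = 0.484 for both).

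Genes listed as markers of the Schwann cell lineage (pan-Schwann genes) did not move together. Whether each of them marks the lineage equally at every stage was not tested. Of 11 pan-Schwann genes, 2 rose and 2 fell (2 and 3 adjusted over the list alone). Fabp7, which encodes the brain fatty acid binding protein, rose by 1.95 (SE 0.28) and Cdh6, a cadherin, by 1.06 (SE 0.15). The neuregulin receptor gene Erbb3 fell by 1.33 (SE 0.25) and the calcium-binding protein gene S100b by 1.33 (SE 0.26). The list's median change was 0.01 and its mean -0.005, and camera gave an adjusted p of 0.808. The mean of the 15 myelin genes exceeded that of the 11 pan-Schwann genes by 2.00 ± 0.02 in control nerves and lay under it in dKO nerves (-0.84 ± 0.68), a change of -2.84 (SE 0.40). The exact two-sided permutation test gave p = 0.1 with n = 3 per group, the smallest p that 3 against 3 arrays allow. Without dKO 1, whose difference was -0.05 against -1.27 and -1.20 in dKO 2 and dKO 3, the median change of the myelin list was -3.66.

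Of 18 genes for axon contact, the basal lamina and their receptors, 8 fell and 1 rose, the same counts as adjusted over the list alone. The axon adhesion genes Nrcam and Cadm3 fell by 1.76 (SE 0.18) and 1.64 (SE 0.24), and the scaffold gene Mpp6 fell by 1.70 (SE 0.23). The gene that rose, the insulin-like growth factor receptor gene Igf1r, changed by 0.75. That call was lost without any one of the 3 control arrays, dKO 1 or dKO 2 (adjusted p up to 0.0958). Without control 2 or dKO 2, 5 genes of the list were called lower. The list passed in camera (median -0.55, and -0.30 without dKO 3, adjusted p = 0.000406), and not with an estimated correlation (adjusted p = 0.614).

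Of 17 genes of immature, non-myelinating or repair Schwann cells, 8 rose and 1 fell (8 and 2 adjusted over the list alone). Hey2, a Notch pathway repressor, was under the limit on 2 of the 3 control arrays and at 6.91 ± 0.62 in dKO. With those values set to the limit it was 7.43-fold higher (adjusted p = 0.000403). Gap43, a growth-associated protein gene, rose from 5.82 ± 0.24 to 8.87 ± 0.31 (log2 change 3.05, SE 0.20, adjusted p = 0.000106). Egr1 rose by 1.35 (SE 0.20), and Gdnf, a neurotrophic factor gene under the limit on all control arrays, was at least 1.83-fold higher. The gene that fell was Hey1 (-1.04). Jun, a regulator of the repair state after nerve injury, had a log2 change of 0.27 (SE 0.16, adjusted p = 0.277), and of 0.42 with its probe sets averaged. The list passed in camera (median 0.41, and 0.24 without dKO 3, adjusted p = 0.0368), and not without control 3 (adjusted p = 0.0766), under a low-value limit of 6 (adjusted p = 0.0683) or with an estimated correlation (adjusted p = 0.484). Without control 1 or dKO 2, 5 genes were called higher, and without control 3 or dKO 3, 3 and 2 were called lower.

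Wnt and beta-catenin targets moved in both directions, with 2 of 12 higher and 2 lower, the same counts as over the list alone. Apcdd1, an inhibitor of Wnt signalling, rose by 1.34 (SE 0.26, 3 of 5 probe sets called) and the cell surface receptor gene Cd44 rose from 8.25 ± 0.16 to 9.25 ± 0.11 (1 of 3 called). Nkd1, another inhibitor, fell by 1.17 (SE 0.22) and the R-spondin receptor gene Lgr5 fell from 7.70 ± 0.09 to 6.70 ± 0.30. Axin2, a commonly used readout of the pathway, had a log2 change of -0.66 (SE 0.24, adjusted p = 0.0831), but its other probe set changed by -0.07 and the average of both by -0.37. Ccnd1, which encodes cyclin D1, had a log2 change of -0.13 (SE 0.13, adjusted p = 0.522), and of -0.23 with its probe sets averaged. The list did not pass (median -0.13, adjusted p = 0.609).

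Cell cycle genes rose in part. Of 29 tested, 7 rose and 0 fell (8 and 0 over the list alone), with a median log2 change of 0.36. Ccne1, which encodes cyclin E1, rose by 1.24 (SE 0.25) and Rrm2, a subunit of ribonucleotide reductase, by 0.90 (SE 0.14). Mcm6 and Nusap1 rose by 0.61 each, calls lost without control 2 or dKO 1 for Mcm6 (adjusted p up to 0.0713) and without control 2 or control 3 for Nusap1 (adjusted p up to 0.0743). With its probe sets averaged, Nusap1 had a change of 0.20, not past the threshold. Without control 2, control 3 or dKO 1, the number called was 2, 4 and 4. The list passed in camera (adjusted p = 0.00136), and not with an estimated correlation (adjusted p = 0.484). Of 7 cyclin-dependent kinase inhibitors, 2 fell and 1 rose, the same counts as over the list alone, and the list did not pass (median -0.08, adjusted p = 0.581). Cdkn1a, which encodes p21, fell from 11.74 ± 0.45 to 9.54 ± 0.35 (log2 change -2.21, SE 0.26, adjusted p = 0.000879), and its other probe set fell by 2.63 (SE 0.23). Cdkn1b, which encodes p27, fell by 1.26 (SE 0.20), and Cdkn2b, which encodes p15, rose by 1.13 (SE 0.22).

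Of 17 p53 targets, 6 rose and 1 fell, the same counts as over the list alone. The one that fell was Cdkn1a. Sesn2, a stress-induced metabolic regulator, rose by 1.67 (SE 0.26, 1 of 2 probe sets called, 1.07 with both averaged). Zmat3 rose by 1.19 (SE 0.18) and the death receptor gene Fas by 1.04 (SE 0.17). The list's camera call (median 0.24, and 0.43 without dKO 1, adjusted p = 0.0477) was lost without control 2, control 3 or dKO 2 (adjusted p = 0.110, 0.0686 and 0.117) and under a limit of 6 (adjusted p = 0.177). It was also lost with a replicate block (adjusted p = 0.0504) and with an estimated correlation (adjusted p = 0.614).

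Among 17 apoptosis genes, 5 rose and 0 fell (5 and 1 over the list alone). Casp1, which encodes the inflammatory caspase that processes interleukin-1 beta, rose from 5.90 ± 0.42 to 9.96 ± 0.13 (log2 change 4.06, SE 0.21, adjusted p = 4.61e-05). Bid rose by 1.39 (SE 0.25, 1 of 2 probe sets above the limit called, 0.72 with its probe sets averaged) and Casp8 by 0.69 (SE 0.15). Apaf1 rose by 0.65, a call lost without control 1, control 3, dKO 1 or dKO 3 (adjusted p up to 0.0923). Diablo rose by 0.53, a call lost without control 1, control 2, dKO 1 or dKO 2 (adjusted p up to 0.110). Without control 1 or dKO 1, 3 genes of the list were called higher, and without control 1 or control 2, 1 was called lower. The list did not pass in camera (adjusted p = 0.581) but did in fry (adjusted p = 0.0182, direction up), and its median was -0.07 while its mean was 0.32 and camera's direction was up.

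Of 14 histone deacetylases, 4 fell and 1 rose, the same counts as over the list alone. Beyond Hdac1 and Hdac2, which were targeted, the NAD-dependent deacetylase Sirt2 fell by 1.03 (SE 0.13) and Hdac10 by 0.66 (SE 0.14). The Hdac10 call was lost without control 2 (adjusted p = 0.0561), and its change was -0.38 with its probe sets averaged. Hdac6, the tubulin deacetylase, rose by 0.69, a call lost without dKO 2 (adjusted p = 0.0593). The list passed in camera (median -0.28, adjusted p = 0.0387), and not without control 2 (adjusted p = 0.0522), without dKO 3 (adjusted p = 0.0618), with probe sets averaged (adjusted p = 0.0988) or with an estimated correlation (adjusted p = 0.484). Without Hdac1 and Hdac2 the list's adjusted p was 0.293.

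Subunits of the complexes that contain HDAC1 and HDAC2 rose in part, with 4 of 20 higher and 0 lower, the same counts as over the list alone. Ing2 and Sap30, subunits of the SIN3 complex, rose by 1.53 (SE 0.17) and 1.37 (SE 0.22). Sin3a, its scaffold, rose by 0.84 (SE 0.20), a call lost without control 2, dKO 1 or dKO 2 (adjusted p up to 0.0755). Ing1 rose by 0.59 (SE 0.15, 1 of 3 probe sets called, 0.23 and not past the threshold when averaged), a call lost without control 1, control 3, dKO 1 or dKO 3 (adjusted p up to 0.0743). The list's camera call (median 0.28, and 0.18 without dKO 3, adjusted p = 0.0475) was lost without control 1, control 3, dKO 1 or dKO 2 (adjusted p = 0.0611, 0.0662, 0.0535 and 0.0643). It was also lost under a limit of 6 (adjusted p = 0.0646), with probe sets averaged (adjusted p = 0.130) and with an estimated correlation (adjusted p = 0.484).

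Of 15 neuronal genes repressed by the transcription factor REST, 4 rose and 2 fell, the same counts as over the list alone. Stmn3, a microtubule regulator, rose by 2.61 (SE 0.41), Snap25, a synaptic vesicle fusion protein gene, by 1.45 (SE 0.19), and Scn3b, a sodium channel subunit gene, by 1.30 (SE 0.18). Gria2 rose by 0.88, a call lost without control 1, control 2, dKO 1 or dKO 2 (adjusted p up to 0.145). Scg3, a secretory granule protein gene, fell by 2.00 (SE 0.23) and the synaptophysin gene Syp by 0.98. The list did not pass (median 0.18, adjusted p = 0.635).

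**Figure D2:**
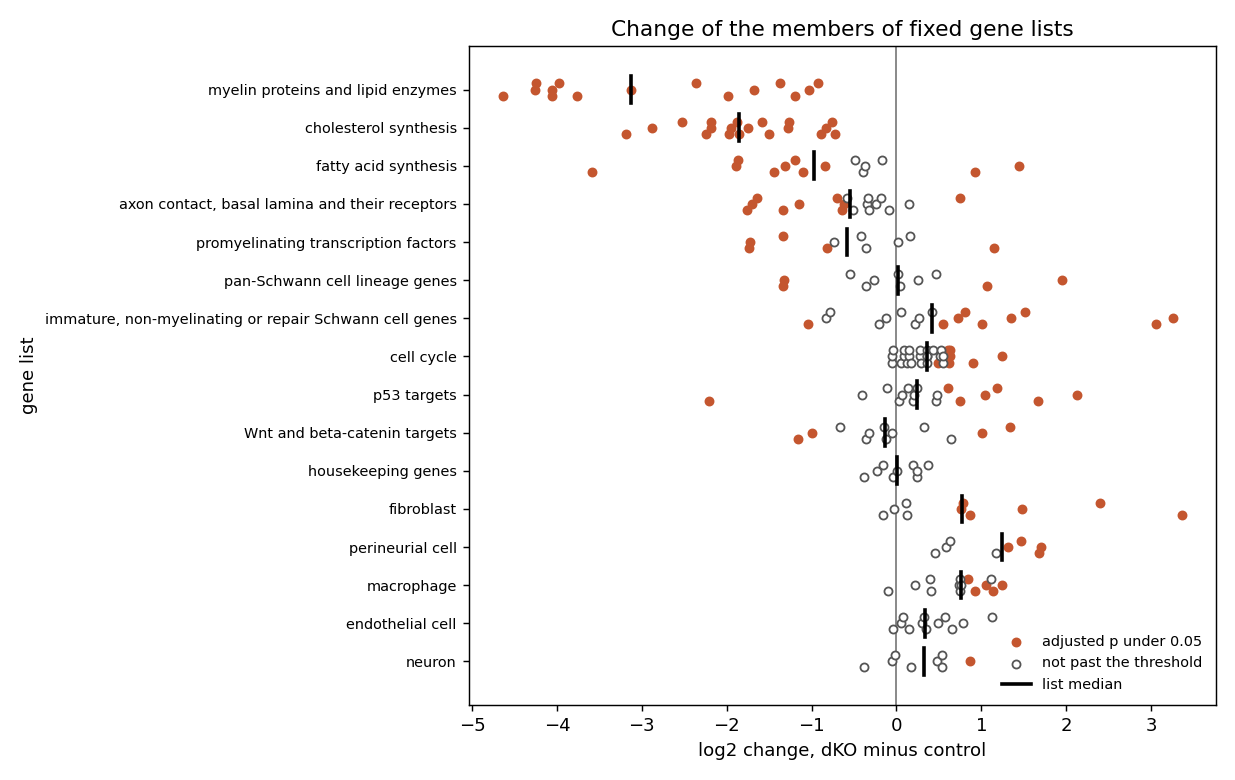
Log2 change, dKO minus control, of each tested gene (horizontal axis) in 16 of the gene lists (vertical axis), with filled points for an adjusted p under 0.05, open points for genes not past it and a black bar for the list median. All 15 myelin genes and all 19 cholesterol synthesis genes lie below 0, with medians of -3.12 and -1.86, whereas the 9 housekeeping genes lie from -0.38 to 0.37.

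Markers of other cell types in the nerve were higher in dKO samples for several lists. Of 10 fibroblast genes, 6 rose and 0 fell (6 and 0 over the list alone). Dpt, the dermatopontin gene, was under the limit on 2 of the 3 control arrays and at 6.98 ± 0.63 in dKO, which is 7.46-fold higher with those values set to the limit. Fbln1, a fibulin gene, rose by 1.48 (SE 0.27) and Pdgfra, a platelet-derived growth factor receptor gene, by 0.78 (SE 0.15). Dcn, the decorin gene, rose by 0.86 (SE 0.20), a call lost without control 2 or dKO 2 (adjusted p up to 0.0618). Without control 2 or dKO 2, 3 fibroblast genes were called. The collagen genes Col1a1 and Col3a1 had log2 changes of 0.12 and 0.11, not past the threshold. Of 8 perineurial genes, 4 rose and 0 fell (5 and 0 over the list alone). These were Moxd1, Cldn1 and Tenm2, with log2 changes of 1.31 to 1.70, and Mpzl2, under the limit on all control arrays and at least 1.57-fold higher. With probe sets averaged, the change was 0.83 for Cldn1 and 0.78 for Tenm2. The perineurium had been removed before extraction, and the mean over this list ran from -0.57 to 0.57 among the control arrays, relative to their mean. The number called was 1 without control 2 or dKO 1, and 2 without dKO 2 or dKO 3. The calls of Cldn1, Mpzl2 and Tenm2 were those lost (adjusted p up to 0.0584, 0.116 and 0.0781), Mpzl2 also without control 1. Both lists passed in camera (median 0.77, adjusted p = 0.0115 for fibroblasts, and 1.24, or 0.79 without control 1, adjusted p = 0.00702 for perineurial cells). Neither passed with an estimated correlation (adjusted p = 0.614 and 0.568).

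Of 14 macrophage genes, 5 rose and 0 fell (6 and 0 over the list alone). The lysosomal protease gene Ctss rose by 1.25 (SE 0.20), the complement genes C1qc by 1.13 (SE 0.31) and C1qa by 0.84 (SE 0.17), and Aif1 and Tyrobp by 1.06 and 0.92. The number called was 3 without control 1 or dKO 2, and 2 without control 2 or control 3. The calls of Aif1, C1qc and Tyrobp were those lost (adjusted p up to 0.0858, 0.104 and 0.136), and the Tyrobp change was as low as 0.58. The mean over the list lay 1.34 above the control mean in dKO 3, against 0.36 in dKO 1 and 0.49 in dKO 2. The list passed in camera (median 0.76, and 0.40 without dKO 3, adjusted p = 0.00267), and not with an estimated correlation (adjusted p = 0.688).

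Of 9 pericyte and smooth muscle genes, 4 rose and 0 fell (5 and 0 over the list alone). The receptor gene Notch3 and the potassium channel genes Kcnj8 and Abcc9 rose by 1.34 (SE 0.16), 1.32 (SE 0.19) and 0.69 (SE 0.13). Rgs5 rose by 0.64, a call lost without any single array (adjusted p 0.0578 to 0.118). The pericyte list did not pass in camera (median 0.64, adjusted p = 0.0542). It passed there without dKO 2 (adjusted p = 0.0337), without the low-value limit (0.0266) and with a replicate block (0.0465). With arrays centred on their medians over the tested genes it passed in camera too (adjusted p = 0.0452). It passed in fry (adjusted p = 0.0160, direction up). Of 12 endothelial genes 0 were called in limma, also over the list alone, and 4 had an unadjusted p under 0.05. Tek and Cldn5 had log2 changes of 1.12 and 0.57 (adjusted p = 0.114 and 0.104). The Tek change was 0.54 without control 1, and Tek gained a call with a replicate block. Cldn5 had a change of 0.37 without dKO 3 and passed without dKO 1 (adjusted p = 0.0424). The endothelial list did not pass in camera (median 0.34, adjusted p = 0.0764), and passed without control 2 or dKO 1 (adjusted p = 0.0431 and 0.0399), without the low-value limit (0.0420) and with a replicate block (0.0429).

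Of 8 neuron markers, 1 rose, the ubiquitin hydrolase gene Uchl1 (0.87, SE 0.19), and the list did not pass (median 0.32, adjusted p = 0.527). Without control 2, 2 neuron markers were called. Of 6 adipocyte genes, 1 rose, the fatty acid binding protein gene Fabp4 (2.30, SE 0.39, with changes of 1.06 to 2.37 on its 3 probe sets), with a list median of 0.003 (adjusted p = 0.691). Of 9 skeletal muscle genes, 2 rose (list median 0.19, adjusted p = 0.527). These were Actn3 (2.60, SE 0.28, 1 control array under the limit) and Mylpf (0.62, SE 0.16), and the Mylpf call was lost without any one of the 3 control arrays, dKO 2 or dKO 3 (adjusted p up to 0.107). For these 3 lists the counts over the list alone were the same. Among 5 T cell, 4 mast cell, 3 red blood cell and 4 sex-linked genes 0 were called in limma, also over the list alone, and 0 had an unadjusted p under 0.05. Their camera adjusted p was 0.635, 0.609, 0.741 and 0.691. The members with the smallest p were Cd4 and Cd8a (-0.26 and -0.21), Cpa3 and Cma1 (0.36 and 0.31), Alas2 and Hbb-y (-0.20 and -0.09), and Xist and Uty (2.20 and -1.35). With 1 array left out these ran from 0.77 to 4.48 for Xist, -2.43 to -0.66 for Uty, -0.77 to 0.16 for Alas2, -0.13 to -0.05 for Hbb-y, 0.11 to 0.51 for Cma1, 0.18 to 0.59 for Cpa3, -0.37 to -0.16 for Cd4 and -0.30 to -0.09 for Cd8a. Cpa3 was under the limit on 2 of the 3 control arrays, and 1.02-fold higher with those values set to the limit.

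Of 9 melanocyte and other neural crest genes, 3 fell and 2 rose (4 and 2 over the list alone), with a median of 0.13, a mean of -0.20 and camera's direction down (adjusted p = 0.635). The pigment cell genes Tyrp1 and Mitf fell, with log2 changes of -1.83 (SE 0.30, 1 dKO array under the limit) and -1.63 (SE 0.21). Pmel fell by 1.22, a call lost without control 2, control 3, dKO 2 or dKO 3 (adjusted p up to 0.0956). Tfap2a rose by 1.32 (SE 0.22), and by 2.91 with its 3 probe sets averaged. Twist1 rose by 1.35, a call lost without control 1, control 2 or any one dKO array (adjusted p up to 0.135), with changes of 0.86 to 1.69.

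Stress and immune lists did not pass in camera. Of 13 endoplasmic reticulum stress and ATF4 targets, 3 rose (list median 0.01, adjusted p = 0.581). These were Ddit4 (1.25, SE 0.23), Sdf2l1 (0.70, SE 0.16) and Dnajb9 (0.49, SE 0.13). The Sdf2l1 call was lost without control 1, control 2 or dKO 2 (adjusted p up to 0.0590) and the Dnajb9 call without any single array (adjusted p 0.0502 to 0.0898). Without control 1, control 2 or dKO 2, 1 gene of that list was called higher, and without dKO 3, 1 was called lower. Of 11 chemokine and cytokine genes, 3 rose (list median 0.19, adjusted p = 0.527). These were Il33 (1.74, SE 0.21), Icam1 (0.85, SE 0.22) and Csf1 (0.75, SE 0.18). The Icam1 call was lost without control 1, dKO 2 or dKO 3 (adjusted p up to 0.0958) and the Csf1 call without control 2, control 3 or dKO 1 (adjusted p up to 0.0743). The Csf1 change was 0.45 with its probe sets averaged. Counts over the list alone were the same for both lists.

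Of 9 interferon-stimulated genes, 1 was lower, Ifit2 (-0.62, SE 0.18, adjusted p = 0.0442), a call lost without control 2, control 3 or any one dKO array (adjusted p up to 0.137). Over the list alone 0 passed, and without dKO 1, 1 gene was called higher and 0 lower. The median of the interferon list was 0.21, and -0.26 without dKO 3, and camera's direction was up (adjusted p = 0.807). Of 12 immediate early genes, 3 rose and 1 fell (4 and 1 over the list alone, list median 0.01, adjusted p = 0.598). Ier3 rose by 1.51 (SE 0.18) and Egr1 by 1.35. Ier2 rose by 0.76, a call lost without control 1, control 3, dKO 2 or dKO 3 (adjusted p up to 0.0799). Ccn1 had a log2 change of -0.94 on a probe set that can cross-hybridise. Without such probe sets its change was -0.33 and with probe sets averaged -0.62, both not past the threshold. Without control 3, 2 immediate early genes were called lower. Of 9 housekeeping genes 0 were called in limma, also over the list alone, and 1 had an unadjusted p under 0.05 (list median 0.01, adjusted p = 0.871), with log2 changes from -0.38 to 0.37. B2m and Sdha, with the smallest p, had log2 changes of 0.37 and -0.23. With its probe sets averaged, the Sdha change was -0.06.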

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

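Each test of an explanation for the fall of the myelin list was chosen after the result was seen.

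Signal that the comparisons by gene did not use was found on probe sets without a single gene name. Of 5541 tested probe sets not named here, 254 (4.58%) changed between dKO and control nerves, 126 higher and 128 lower, and 193 of them at least 2-fold. Of 716 tested probe sets with several gene names, 69 (9.64%) changed, 39 higher and 30 lower.

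The 6 arrays can be split 3 against 3 in 10 ways, so the share of splits that give as many genes cannot fall under 0.05. The real split gave 3198 changed genes and the highest of the other splits 4, so 1 split gave as many. For genes changed at least 2-fold the real split gave 1508, the highest other 4, and again 1 split gave as many. Every other split has dKO and control arrays on both sides, so the difference between the groups widens the spread within each side. Counts of the other splits therefore do not estimate the number of false calls. The split with 4 genes put control 1, control 3 and dKO 1, the arrays with high Y-linked expression, against the rest.

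The fall of the myelin list could come from a smaller share of Schwann cell RNA in dKO nerves, from the scaling between arrays, or from lower expression of myelin genes in the Schwann cells present. A smaller share as the whole cause would lower the pan-Schwann genes as much. The myelin minus pan-Schwann difference changed by -2.84 (SE 0.395), which argues against it. The changes of single pan-Schwann genes ran from -1.33 to 1.95 (SD 0.963), however, so their mean does not measure the share by itself. A smaller share as part of the cause would raise the markers of every other cell type alike. The medians of the fibroblast, perineurial, endothelial, pericyte and macrophage lists spanned 0.903, within the largest interquartile range of 1.21 among their members, so this part cannot be told apart from a change within cells. The perineurial list may also follow how much perineurium was left after its removal. Scaling as a cause would move housekeeping genes too, and their median change was 0.01 (SD 0.253), which argues against it. A smaller share as part of the cause stays open, and lower expression of myelin genes per Schwann cell was not tested by itself.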

How the results depend on the processing

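The Xist covariate and the histone deacetylase list without its targeted genes were chosen after seeing the data. Of 535 results under alternatives, 492 were kept, 29 lost and 12 gained a call, and 2 counts moved by over 1.5 times. Kept means on the same side of the threshold or, for gene counts, within 1.5 times. For the myelin minus pan-Schwann difference it means within 1 SD of the dKO arrays. With a call in either fit 0 changed direction, but a change of sign without a call was counted as kept. By the same rule, 1777 of 1873 results for single named genes stayed, 93 lost and 3 gained a call, and 0 reversed with a call. Alas2, not called, went from -0.20 to 0.16 without dKO 3 and was counted as stayed. Both tallies include quantile normalization, which gave 126 of the 1777. Quantile normalization changed no call and moved no value by over 0.00117, because the arrays were already nearly equal in distribution, so it tests nothing. The number of changed genes was 2178 to 2916 with 1 array left out (1379 to 1604 at least 2-fold), and 5219 (2530 at least 2-fold) when every one of 27718 probe sets was tested, since more features were counted. Where no reason is given, the cause was not tested. Same-numbered arrays had correlations of 0.039, -0.122 and -0.235 between their deviations from the group means. Differently numbered arrays had -0.160 to 0.215. These values gave no sign that the replicate numbers pair the arrays, but 3 arrays per group cannot exclude it. A replicate block gave 2557 changed genes (1516 at least 2-fold), and adjusted p = 0.0504 for p53 targets, 0.0429 for endothelial and 0.0465 for pericyte genes. Arrays carry no depth, and signal near background limits the fold of dim genes.

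With an estimated correlation the adjusted p was 0.484 for the myelin, cholesterol, fatty acid, immature Schwann, cell cycle, histone deacetylase and HDAC1/2 complex lists, 0.614 for axon contact, p53 and fibroblast, 0.568 for perineurial and 0.688 for macrophage genes. Under a limit of 6 it was 0.0683 for immature Schwann, 0.177 for p53 and 0.0646 for HDAC1/2 complex genes. Without the limit it was 0.0420 for endothelial and 0.0266 for pericyte genes. With arrays centred on their medians over the tested genes it was 0.0452 for pericyte genes. With probe sets averaged it was 0.0366 for promyelinating factors, 0.0988 for histone deacetylases and 0.130 for HDAC1/2 complexes, and with an intensity trend 0.0458 for promyelinating factors. Histone deacetylases without Hdac1 and Hdac2 gave 0.293. With each array left out in turn the adjusted p ranged from 0.0225 to 0.176 for promyelinating factors, 0.0223 to 0.0766 for immature Schwann, 0.0215 to 0.117 for p53, 0.0290 to 0.0618 for histone deacetylases, 0.0398 to 0.0662 for HDAC1/2 complexes, 0.0399 to 0.320 for endothelial and 0.0337 to 0.0938 for pericyte genes.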

Other observations

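Tests of a background shift, of residual expression, of lower p53 activity and of Xist as a covariate were chosen after the results were seen. The others in this part were set before, and the genes named in the next paragraph were chosen after their values were seen.

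A small group of genes went from under 4 on all control arrays to 6 or more on all dKO arrays. These 11 genes were Csn3, Col25a1, Cadps, Pgbd5, Dynlrb2, Scn3a, Clca3a2, Ttpa, Cntnap5a, Rhpn2 and Clca3a1. With control values set to the limit, Scn3a, a neuronal sodium channel gene, was at least 5.93-fold higher and Ttpa, which encodes the vitamin E transfer protein, at least 5.88-fold higher. The paralogs Clca3a1 and Clca3a2 were at least 7.12-fold and 6.21-fold higher. In the opposite direction Marveld3 alone met the same limits.

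The switched-on genes could reflect a background shift between the arrays, neuronal RNA carried into the dKO nerves, or loss of repression by HDAC1 and HDAC2. A shift of the background in general would raise dim genes. The 3343 genes under the limit on all control arrays, whatever their dKO values, had a median change of -0.015 (interquartile range 0.234). No general rise of dim genes was thus left in the deposited values. The arrays had been made equal in distribution before they were deposited, however, so such a rise could hardly appear. A background shift therefore stays open. Neuron markers had a median change of 0.323 (interquartile range 0.565), but 7 of the 8 were above the limit in control nerves (Nefl at 10.17 ± 0.33, against 10.71 ± 0.27 in dKO), a baseline that would hide added RNA, so the bound set on their change was not a fair test and neuronal RNA stays open. Loss of repression predicts more genes switched on than off, and 11 were on against 1 off (exact two-sided binomial p = 0.00635). Residual transcripts of other cells and of undeleted Schwann cells may however keep genes from reaching the floor, and among genes changed at least 8-fold 42 were higher and 36 lower (exact two-sided binomial p = 0.572), so the excess of switched-on genes does not show loss of repression.

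Cdkn1a fell while 6 of the 16 other p53 targets rose and 10 did not pass the test. A single faulty probe set is argued against by the other Cdkn1a probe set, which had a log2 change of -2.63 (SE 0.228). Lower p53 activity would lower the other targets. Of the 16, 6 were called higher and 0 lower (exact two-sided binomial p = 0.0312), which goes against it. That test takes genes as independent, however, whereas the p53 list had an estimated correlation of 0.136. The 16 targets had a median change of 0.356, within their interquartile range of 0.698. Without control 2 or dKO 2, only 4 of them were called higher. Rises in other cells of the nerve could also hide a fall in Schwann cells, so lower p53 activity is not excluded.

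Linked alleles around the targeted genes may change genes beside them, and 21 of the 80 nearest tested genes (26.25%) were called, against 21.94% of other genes (Fisher's exact two-sided p = 0.345). By locus these were 7 of 40 beside Hdac1 and 14 of 40 beside Hdac2, which leaves this open.

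Both sexes were in both groups, in unequal numbers. With the Xist level of each array as a covariate 2327 genes changed, 2301 of them among the 3198 called without it. For the covariate itself 4 genes were called. Xist was among the genes tested and was fitted on its own level, so its own call there would be by construction.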
